A study of Mus musculus with 2 samples.

How the data were processed

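Single-cell RNA sequencing was done on cardiomyocytes of P1 mice infected with adenovirus carrying LacZ (1 library) or 4F (1 library), 2 libraries in all. LacZ is a bacterial gene commonly used as a control cargo. 4F stands for the cell cycle factors CDK1, CDK4, CCNB and CCND, per the labels; which B and D cyclins were used is not given in the sources used here. Per the labels' protocols, the cells were passed through a filter, captured in droplets with a Chromium version 3 kit, and sequenced to at least 50000 reads per cell. The same protocols state that reads were mapped and counted with Cell Ranger 3.1.0 at default parameters, that the libraries were combined with its aggregation step, and that the result was processed in R with Seurat 3.1.3. The genome is named in different ways: GRCh38, a human assembly, per the labels' protocols, and mm10 per the submitters' processing notes. The gene identifiers in the table are mouse Ensembl identifiers. All 218 were found in the GENCODE M21 annotation of GRCm38 (mm10), 216 with the same symbol, and coordinates are given on that build.

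The values come from 1 table of 218 genes by 24 numbered clusters of cells. For each gene and cluster the authors deposited an average, a signal that is never negative and whose scaling is not stated. They also deposited a log2 fold change and a p-value, whose test and adjustment are not stated in the table. The table has 0 columns that name a library, so cells of LacZ and 4F are not separated in any value, and no comparison of LacZ with 4F was made. All 218 genes had a positive log2 fold change in cluster 1 in the authors' deposited table, the genes stood in order of that cluster's p-value, and the highest average of every gene was at least 1. The genes are therefore a selection on cluster 1, and other genes are not analysed here. The name of the deposited values, graph-based features, points to graph-based clusters. The settings of the clustering, the rule that numbered the clusters and the number of cells in each are not given in the sources used here. How doublets were treated and how cells were filtered are not given there either.

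The depth behind the averages was recovered from the table. Each log2 fold change was modelled as the log2 ratio between a cluster and all other clusters of (1 + summed counts) over (1 + summed weight), where the weight of a cluster is the number that turns its averages into counts. Least squares gave 24 weights with a misfit below 1e-10, and weights fitted on every second gene predicted the log2 fold changes of the other genes within 1e-10. With these weights, 5232 of 5232 averages times weight were whole numbers within 0.001. Those whole numbers, from 33 to 2502470, were used as counts. An average is thus read as counts per unit weight. The weight is the authors' scaling and equals neither a number of cells nor, for certain, a share of all transcripts. Averages carry exact Poisson 95% intervals, and ratios between clusters carry 95% intervals from the exact conditional binomial distribution. These cover counting error only, not differences between cells, cultures or animals. No count model was fitted and no p-value of this work's own was computed, since cells are not replicates and each group has 1 library.

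Genes were called higher or lower in a cluster at the authors' p of 0.05 or less. Of 32 lists fixed before the data were examined, 11 hold cell type markers and 21 hold pathways or complexes. A list with at least 3 members in the table was described by its counts of higher and lower members and by the median of the authors' log2 fold changes. That median was placed among 10000 random lists of the same size drawn from the 218 genes and matched on mean expression in 10 bins, and called when outside the 2.5 to 97.5 percentiles. Percentiles describe this selection of genes, not the transcriptome. Lists with fewer members are given as single genes. In tables simulated with 24 clusters and 218 genes the recovery returned 100% of the counts. With values simulated independently for each gene, the percentile rule called 5% of lists of 18 genes with no shift, 48% of those shifted by 0.5 log2 and 99% of those shifted by 1 log2. The listed genes include large groups that move together, and the lists differ in size. These rates therefore do not carry over to the lists described here.

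Genes were named by a rule fixed before the data were examined. For each cluster it takes the 5 genes with the largest log2 fold change among those with an authors' p of 0.05 or less and a cluster average at or above the median of all averages, 1.26, without predicted genes. It adds the 3 most negative among genes whose mean average reaches the median of the mean averages, and up to 4 members of each list. Cdk1, Cdk4, Ccnb1 and Ccnd1, taken for the 4F factors before the data were examined, are added where listed. Gm42418 is a predicted gene outside this rule and was chosen after its values were seen, as were the ratios between chosen pairs of clusters and the sets of clusters whose correlations are given. A cluster was called cardiomyocyte-like only from the fixed markers, with at least 3 of them higher and no leading genes that go against the name. Similarity between clusters is the Pearson and Spearman correlation of log2(average + 0.01) across genes. Alternatives tried were an absolute log2 fold change of at least 1, p-values of 0.01 and 0.1, and a filter that keeps the 109 genes with a mean average at or above the median. Others were unmatched random lists, ratios of averages with pseudocounts of 0.01, 0.1 and 1, other pseudocounts in the correlations, and the 139 genes left without ribosomal protein and mitochondrially encoded genes. A ratio of averages is log2(average + pseudocount) of a cluster less the mean of that value over the other clusters, each counted alike whatever its weight. These ratios therefore change the reference as well as the pseudocount, and the effects of the 2 changes are not separated. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.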

Results

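Cardiomyocytes of P1 mice were infected with an adenovirus carrying LacZ or with adenoviruses carrying the 4F cell cycle factors, and their transcripts were counted cell by cell. There was 1 library for LacZ and 1 for 4F. The table analysed gives 218 genes in 24 clusters and names no library. The recovered counts summed to 229916397 over the listed genes and to a weight of 595728 over the clusters. Cluster 5 held 30.8% of the weight, cluster 8 held 16%, cluster 7 held 12%, cluster 9 held 8.05%, cluster 11 held 5.56%, cluster 14 held 5.52%, cluster 21 held 4.58%, cluster 12 held 3.72% and cluster 19 held 2.40%. These 9 clusters made up 88.7% of the weight and the other 15 made up 11.3%. The 95% interval of an average had a median half-width of 0.903% of the average in the 9 clusters, with a largest of 12.2%, and a median of 3.23% with a largest of 35.8% in the 15.

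**Figure D1:**
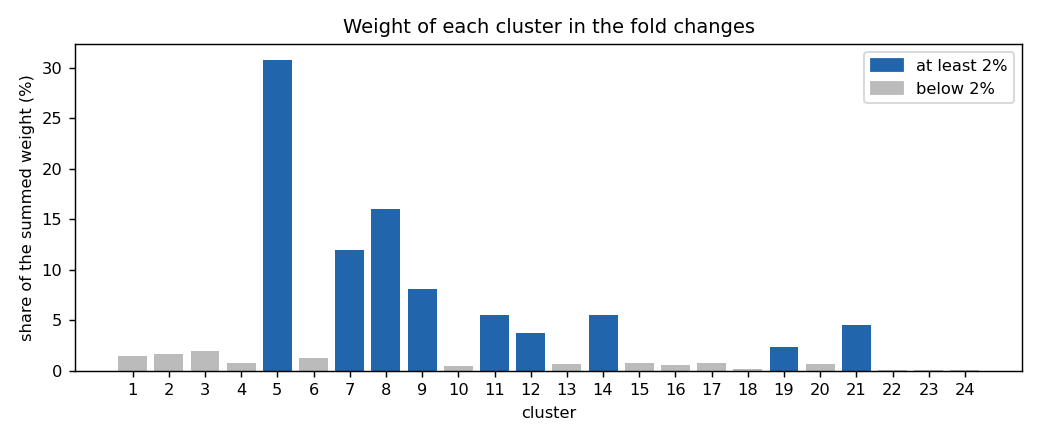
Share of the summed weight (percent, y axis) in each of the 24 clusters (x axis), with bars coloured by whether the share is at least 2%. Cluster 5 has the highest bar at 30.8%, and clusters 22, 23 and 24 stand at 0.0617%, 0.0532% and 0.0318%.

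The purpose of the series, by its title, was to set cardiomyocytes with cell cycle stimulation against cardiomyocytes without it. No column names a library, so no value here belongs to LacZ or to 4F alone, and no cluster is assigned to either. The comparisons are those the table holds, each cluster against all other cells. In the authors' deposited table, 632 pairs of a gene and a cluster were higher and 1169 were lower at p of 0.05 or less. Cluster 21 had 105 genes higher and 90 lower, cluster 8 had 105 and 99, cluster 5 had 101 and 50, cluster 7 had 92 and 64, cluster 9 had 81 and 107, and cluster 14 had 60 and 89. Cluster 11 had 14 genes higher and 131 lower, cluster 19 had 4 and 86, cluster 12 had 2 and 105, cluster 1 had 13 and 0, and clusters 20, 22, 23 and 24 had none in either direction. The clusters were cut from the same cells whose genes are compared, and the genes were selected on cluster 1, so these counts describe the authors' clusters and carry no error across cultures or animals. With an absolute log2 fold change of at least 1 required as well, 113 of the higher pairs were left.

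Cardiac muscle genes separated the large clusters. Of the 16 cardiomyocyte markers 11 were listed, and in the authors' deposited table all 11 were higher in clusters 7 and 9, 9 were higher in cluster 5 and 5 in cluster 11, with none lower in these 4 clusters. The median log2 fold change of the markers in the authors' deposited table was 1.21 in cluster 7, 1.00 in cluster 9, 0.33 in cluster 5 and 0.33 in cluster 11. As ratios of averages with a pseudocount of 0.01, where the other clusters count alike whatever their weight, these medians were 1.63, 1.59, 0.84 and 1.14. The same 11 markers were all lower in clusters 8, 12, 14, 19 and 21, with medians in the authors' deposited table of -4.12, -3.15, -3.85, -3.02 and -3.43. As ratios of averages these medians were smaller in size. They were -3.33, -2.62, -3.3, -2.45 and -2.84 with a pseudocount of 0.01, and -1.72, -1.54, -1.69, -1.49 and -1.56 with a pseudocount of 1. Tnnt2, the troponin T of the cardiac thin filament, had an average in the authors' deposited table of 15.2 in cluster 7, 15.2 in cluster 9, 11.9 in cluster 11 and 10.5 in cluster 5, against 0.566 in cluster 8 and 0.615 in cluster 14. Actc1, cardiac alpha-actin, had an average in the authors' deposited table of 22.4 in cluster 7 and 10.8 in cluster 5, against 0.611 in cluster 8. Clusters 5, 7, 9 and 11 are called cardiomyocyte-like from these markers, and together they held 56.5% of the weight. The call rests on counts of markers past the authors' p. Some clusters below 2% of the weight had higher marker medians than cluster 5 in the authors' deposited table. Among them were clusters 20, 6, 18 and 1 at 0.94, 0.77, 0.62 and 0.57, with 0, 3, 0 and 1 markers higher. The name therefore does not set clusters 5, 7, 9 and 11 apart from these. Clusters 8, 12, 14, 19 and 21 held 32.2% and stay unnamed.

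Of the 10 other marker lists, for fibroblasts, endothelial cells, endocardial cells, smooth muscle cells or pericytes, macrophages, lymphocytes, granulocytes, erythroid cells, epicardial or mesothelial cells, and Schwann or neural cells, no member was among the 218 genes. Leading genes are here the highest among those with a minimum average. None of the genes that led clusters 8, 14, 19 and 21 is in a marker list. In the authors' deposited table the leading genes of cluster 8 were Lgals1, which encodes galectin-1, with a log2 fold change of 1.62 (p = 1.67e-62), and the calcium-binding protein gene S100a11 with 1.13 (p = 4.88e-29), followed by Txn1, Rpl12 and Eef1b2. Cluster 14 was led in the authors' deposited table by Hmgb1 and H2afz, which encode chromatin proteins, with log2 fold changes of 1.04 (p = 2.82e-10) and 0.98 (p = 3.49e-09), then by Txn1, Tmsb10 and S100a11. Cluster 19 was led in the authors' deposited table by the actin-depolymerising factor gene Dstn with 1.18 (p = 1.77e-06), then by S100a11, Tmsb10 and Ppia. In cluster 12 none passed the rule for named genes on the higher side, and the most negative that rule takes were Myl7, Fabp3 and Cryab, with log2 fold changes of -3.91, -3.36 and -3.36 in the authors' deposited table. Summed over the set, clusters 8, 12, 14, 19 and 21 had 3.13 times the Lgals1 of clusters 5, 7, 9 and 11 (95% interval 3.12 to 3.15) and 2.98 times the S100a11 (2.96 to 3.0). The Lgals1 sum does not hold for each cluster alone. It was led by clusters 8 and 21, with averages in the authors' deposited table of 3.79 and 3.63. Cluster 14 had 0.503 times the Lgals1 of cluster 8, and cluster 19 had 2.33 times that of cluster 12. The average of cluster 12 lay below the 0.989 of cluster 5.

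**Figure D2:**
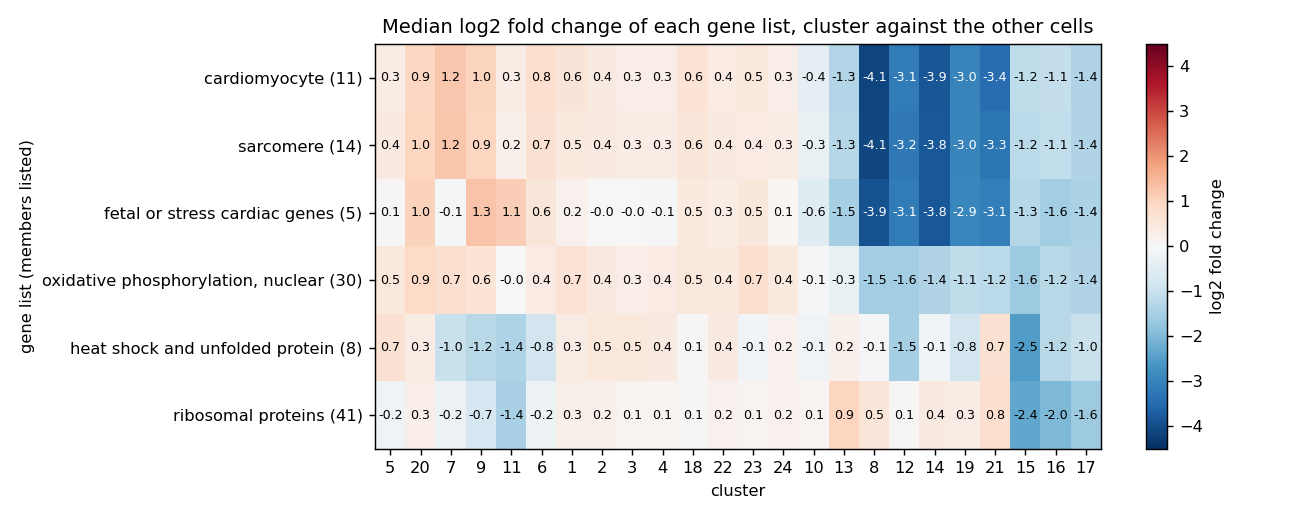
Median log2 fold change of the listed members of 6 gene lists (rows, with the number of members) in each of the 24 clusters (columns, ordered by similar profile), from the authors' deposited table; red is higher and blue lower than in all other cells. The cardiomyocyte and sarcomere rows run from 1.21 and 1.24 in cluster 7 to -4.12 and -4.09 in cluster 8.

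The sarcomere list, proteins of the contractile apparatus and its anchors, had 14 members in the table. Of these, 13 were higher in cluster 9, 12 in cluster 7 and 12 in cluster 5 in the authors' deposited table, with none lower, and the medians of the log2 fold change were 0.95, 1.24 and 0.42. Cluster 11 had 5 higher and 1 lower with a median of 0.24 in the authors' deposited table. All 14 were lower in clusters 8, 12, 14, 19 and 21, where medians in the authors' deposited table ran from -4.09 in cluster 8 to -2.98 in cluster 19. As ratios of averages with a pseudocount of 1 the medians in clusters 8 and 19 were -1.28 and -1.15. In cluster 7 the leading genes in the authors' deposited table were Csrp3, a muscle LIM protein of the Z-disc, at a log2 fold change of 1.66 (p = 3.41e-54), Actc1 at 1.57 (p = 6.58e-48), Fabp3, which binds fatty acids in heart muscle, at 1.37 (p = 6.94e-36), Tnnc1, cardiac troponin C, at 1.37 (p = 7.16e-36) and Des, desmin, at 1.36 (p = 4.83e-35). The cardiomyocyte and sarcomere lists share members, so their counts are not independent. The sarcomere median lay above 99.8% of random lists in cluster 5, and above 97.0% of unmatched ones, which is inside the central range. The cardiomyocyte median there lay above 96.2% of matched lists, also inside it.

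Genes of mitochondrial respiration were higher in clusters 5, 7 and 9 and lower in clusters 8, 12, 14, 19 and 21. Of the nuclear oxidative phosphorylation list, subunits of the respiratory chain and ATP synthase, 30 members were listed. In the authors' deposited table all 30 were higher in clusters 5, 7 and 9, with median log2 fold changes of 0.47, 0.73 and 0.60. All 30 were lower in clusters 8, 12, 14 and 21, with medians in the authors' deposited table of -1.53, -1.55, -1.36 and -1.22, and 27 were lower in cluster 19, with a median of -1.14. In cluster 11 none passed in either direction and the median in the authors' deposited table was -0.03, beside a median of -0.91 over all 218 genes of that cluster. Cox6a2, the heart and skeletal muscle form of a cytochrome oxidase subunit, had the most negative value of the list in cluster 8, with an average in the authors' deposited table of 1.66 in cluster 7 and 0.0517 in cluster 8. For Atp5g1, a subunit of the ATP synthase ring, the averages in the authors' deposited table were 3.87 and 0.773. Of the fatty acid oxidation list, Etfb and Fabp3 were listed, and of the glycolysis list, Aldoa and Eno3; all 4 were higher in clusters 5, 7 and 9. In cluster 7 the log2 fold changes in the authors' deposited table were 0.69 for Etfb (p = 5.29e-09), 1.37 for Fabp3 (p = 6.94e-36), 0.83 for Aldoa (p = 1.18e-12) and 1.24 for Eno3, the muscle enolase (p = 7.87e-29).

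Ribosomal protein genes ran the other way. Of 41 listed, 39 were higher in cluster 8, 38 in cluster 21 and 26 in cluster 14 in the authors' deposited table, with median log2 fold changes of 0.54, 0.77 and 0.40 and none lower. None was higher in the cardiomyocyte-like clusters: 19 were lower in cluster 5, 17 in cluster 7, 37 in cluster 9 and 41 in cluster 11, with medians in the authors' deposited table of -0.17, -0.25, -0.74 and -1.45. As ratios of averages with pseudocounts of 0.01 and 0.1 the median in cluster 5 turned to 0.06 and 0.04. Cluster 12 had 1 higher and cluster 19 had 0, with medians in the authors' deposited table of 0.06 and 0.33. Rpl12 had an average in the authors' deposited table of 3.96 in cluster 8 and 4.30 in cluster 21, against 1.68 in cluster 7 and 0.715 in cluster 11. Rps12 had an average in the authors' deposited table of 5.05 in cluster 8 and 0.887 in cluster 11.

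Heat shock genes were higher in cluster 5, and most of them were lower in clusters 7 and 9. All 8 listed members of the heat shock and unfolded protein list, which are chaperones and co-chaperones, were higher in cluster 5 in the authors' deposited table, with a median log2 fold change of 0.70, a value that 1 of the 10000 random lists reached. In cluster 7, 6 were lower and 2 higher with a median of -1.0 in the authors' deposited table, and in cluster 9, 6 were lower and 1 higher with -1.25. The medians in clusters 7 and 9 lay above 0.03% and 0.04% of random lists. In cluster 11, 7 were lower with a median of -1.38 in the authors' deposited table, but this lay above 17.3% of random lists, inside the central range, beside the -0.91 over all genes there. Hsp90aa1, the stress-inducible cytosolic HSP90, had an average in the authors' deposited table of 3.96 in cluster 5 against 0.750 in cluster 7, 0.662 in cluster 9 and 0.649 in cluster 11. Hspd1, the mitochondrial chaperonin, had an average in the authors' deposited table of 1.12 in cluster 5 and 0.383 in cluster 7. The list did not move as a unit: Hspb1 and Hspb7, small heat shock proteins abundant in muscle, were higher in cluster 7 at 0.54 (p = 8.38e-06) and 1.52 (p = 2.48e-44) on the log2 scale in the authors' deposited table. In cluster 21, 6 members were higher and these 2 were lower, and the median of 0.70 in the authors' deposited table lay above 83.9% of random lists. Cluster 8 had 2 higher and 2 lower, cluster 14 had 1 and 2, cluster 12 had 0 and 6, and cluster 19 had 0 and 5.

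Of the genes taken for the 4F factors, Cdk1, Cdk4, Ccnb1 and Ccnd1, only Ccnd1 was listed. The labels do not say which D cyclin was used, so Ccnd1 may not be the one that the 4F adenoviruses carry. Ccnd1 encodes cyclin D1, the partner of CDK4 in G1, and lies on chromosome 7 from 144929931 to 144939925 on the minus strand of mm10. In the authors' deposited table it was the leading gene of cluster 5, with a log2 fold change of 1.43 (p = 6.55e-67), and of cluster 21, with 1.59 (p = 1.14e-21). The next leading genes of cluster 5 were the stress genes Hsp90aa1, Hspb1, Cryab and Hspe1, and those of cluster 21 were Hmgb2, Lgals1, Hmgb1 and Txn1. It was lower in clusters 6, 7, 8, 9, 11, 12, 15 and 19, and the most negative values in the authors' deposited table were -4.10 in cluster 9 (p = 8.75e-86) and -4.08 in cluster 7 (p = 2.44e-126). The average in the authors' deposited table was 1.82 in cluster 5 (95% interval 1.81 to 1.82), 2.82 in cluster 21 (2.80 to 2.84), 0.0684 in cluster 7 (0.0665 to 0.0704), 0.0645 in cluster 9 and 0.112 in cluster 11. Among the clusters low in muscle genes it was 0.791 in cluster 8, 0.921 in cluster 14, 0.372 in cluster 19 and 0.313 in cluster 12. Whether transcripts from the viral cyclin were counted under Ccnd1 is not stated in the sources used here. Cdk1, Cdk4 and Ccnb1 are not analysed here.

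Of the G2/M list, Hmgb2 and Jpt1 were listed, and they differed. Hmgb2, a chromatin protein abundant in dividing cells, lies on chromosome 8 from 57511907 to 57515999 on the plus strand of mm10. It was higher in clusters 5, 14 and 21 in the authors' deposited table, with log2 fold changes of 0.78 (p = 1e-19), 0.98 (p = 4.08e-09) and 1.24 (p = 1.73e-12). Its average in the authors' deposited table was 0.80 in cluster 5 (95% interval 0.796 to 0.804) and 0.0297 in cluster 7 (0.0285 to 0.0310). Jpt1 was higher in clusters 5 and 7 in the authors' deposited table, at 0.81 (p = 3.84e-21) and 0.44 (p = 0.000414), and lower in cluster 21 at -0.60 (p = 0.0123). The lists for G1/S and S phase, cytokinesis, replication-dependent histones, and cell cycle inhibitors and p53 targets had no member in the table, so no phase of the cycle can be read from it.

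**Figure D3:**
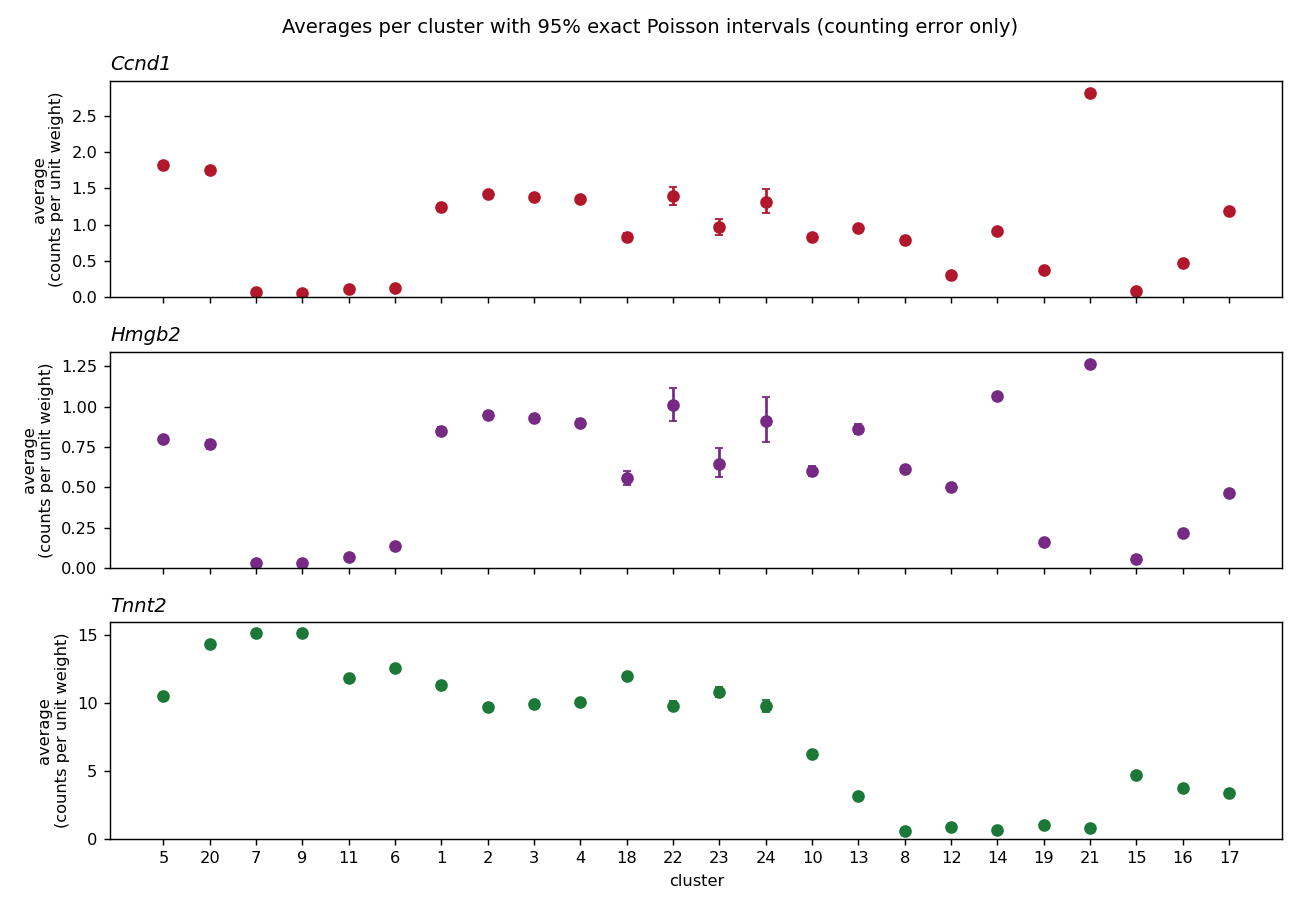
Authors' averages (counts per unit weight, y axis) of Ccnd1, Hmgb2 and Tnnt2 in each of the 24 clusters (x axis, ordered by similar profile), as points with 95% exact Poisson intervals that cover counting error only and are often smaller than the point. Ccnd1 stands at 1.82 in cluster 5 and 0.0684 in cluster 7, while Tnnt2 stands at 10.5 and 15.2.

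**Figure D4:**
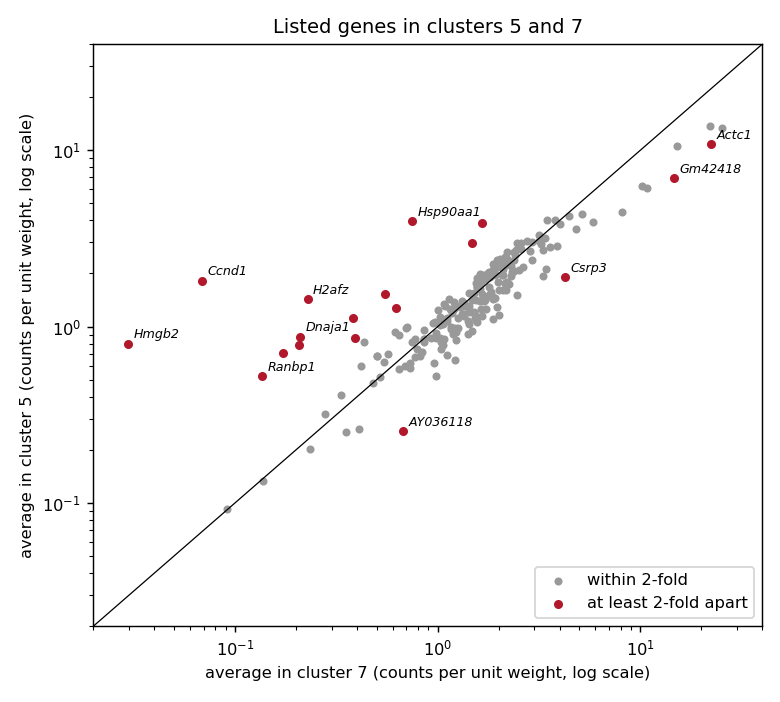
Average of each listed gene in cluster 5 (y axis) against cluster 7 (x axis), both in counts per unit weight on log scales, with the line of equal values; red points are at least 2-fold apart. The pair was chosen after the values were seen, and Hmgb2 and Ccnd1 lie farthest from the line, at 26.9 and 26.6 times higher in cluster 5.

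Cluster 11 was led by Sln, Myl7 and Myl4, and cluster 9 by Myl7 and Myl4. In the authors' deposited table the 3 highest genes of cluster 11 were Sln, sarcolipin, a regulator of the sarcoplasmic reticulum calcium pump in atrial muscle, at a log2 fold change of 2.55 (p = 8.94e-79), and the atrial myosin light chain genes Myl7 at 2.15 (p = 3.56e-52) and Myl4 at 2.09 (p = 6.73e-49). Cluster 9 was led in the authors' deposited table by Myl7 at 1.89 (p = 3.3e-52) and Myl4 at 1.74 (p = 7.68e-44), followed by the myoglobin gene Mb at 1.53 (p = 9.43e-33), and Sln, whose average there is below the minimum for leading genes, stood at 1.90 (p = 3.45e-53). Cluster 11 had 6.01 times the Sln of cluster 7 (95% interval 5.91 to 6.11), 4.06 times the Myl7 (4.04 to 4.09) and 3.78 times the Myl4 (3.75 to 3.82). Myl2, the ventricular light chain, had an average in the authors' deposited table of 10.8 in cluster 7, 9.10 in cluster 9 and 5.12 in cluster 11. Of the fetal or stress cardiac list, 5 genes were listed. Nppa, Tnni1, Myl4 and Myl7 were higher in cluster 9 in the authors' deposited table, with a list median of 1.29, and 3 were higher in cluster 11, with 1.11. Cluster 7 had 2 higher, Nppa and Tnni1, and a list median of -0.08 in the authors' deposited table, and cluster 5 had 1 higher, Tnni1, and 1 lower, Dstn, with 0.07. As ratios of averages with pseudocounts of 0.01, 0.1 and 1 the median turned to 0.83, 0.71 and 0.29 in cluster 7. In cluster 5 it became 0.75, 0.65 and 0.36. Clusters 8, 14 and 19 had 4 lower and 1 higher, Dstn, and clusters 12 and 21 had 4 lower. Of the calcium handling list, Pln and Sln were listed. Pln, phospholamban, was higher in clusters 5, 7, 9 and 11 in the authors' deposited table, from 0.21 (p = 0.0272) in cluster 5 to 1.26 (p = 2.12e-21) in cluster 9.

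Clusters 1 to 4, 6 and 18 were led by AY036118, Cdk8 and Cmss1, and clusters 1 to 4 and 6 also by Camk1d. In cluster 1 of the authors' deposited table the log2 fold changes were 3.29 for AY036118 (p = 8.95e-47), 2.91 for Cdk8 (p = 1.41e-32), 2.74 for Cmss1 (p = 9.46e-28) and 1.89 for Camk1d (p = 1.02e-09). Gm42418, chosen after its values were seen, was higher in cluster 1 at 2.17 (p = 2.54e-14) in the authors' deposited table, with an average in the authors' deposited table of 52.9 against 6.92 in cluster 5. Gm42418 and AY036118 are long noncoding RNA genes that overlap on opposite strands of chromosome 17 in mm10, from 39846958 to 39848788 on the plus strand and from 39847113 to 39848035 on the minus strand. The other 3 are protein-coding and lie on other chromosomes: Cdk8 on chromosome 5 from 146231230 to 146302874, Cmss1 on chromosome 16 from 57302000 to 57606864 and Camk1d on chromosome 2 from 5293457 to 5714515. Overlapping genes cannot be told apart unless counting used the strand, which the labels do not state. Against cluster 5, these 5 genes were the only ones at least 2 times higher in cluster 1. Cluster 6 also had 3 cardiomyocyte markers higher, and its Pearson correlations with clusters 7, 9 and 11 were 0.90, 0.92 and 0.90. Its 4 leading genes were of this set, followed by Nppa, a cardiomyocyte marker. It stays unnamed, although the 4 genes are in no marker list and name no other cell type.

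Clusters 10 and 13 had 8 genes higher each and none lower. Cluster 10 was led in the authors' deposited table by Lgals3, which encodes galectin-3, at a log2 fold change of 4.24 (p = 1.5e-35) and by Fth1, the ferritin heavy chain, at 2.51 (p = 1.6e-07), followed by AY036118, Cmss1 and Camk1d. The average of Lgals3 in the authors' deposited table was 2.89 in cluster 10 (95% interval 2.83 to 2.96) and 0.240 in cluster 1. Of the oxidative stress list, Fth1 and Prdx1 were listed, and Prdx1, a peroxiredoxin, was also higher in cluster 10, at 1.58 (p = 0.0228) in the authors' deposited table. Cluster 13 was led in the authors' deposited table by Lgals1 at 1.78 (p = 0.00441) and S100a11 at 1.63 (p = 0.00937), followed by Cmss1, AY036118 and Txn1. Of the mitochondrially encoded list, mt-Nd6, a subunit of complex I, was listed. It was the 1 gene higher in cluster 16, at 3.27 (p = 1.65e-18) in the authors' deposited table, and it was also higher in clusters 3, 6, 9, 11, 15 and 17. In the authors' deposited table, clusters 15, 16 and 17 had 185, 4 and 156 genes lower and 3, 1 and 1 higher. Their medians over all genes were -2.04, -1.62 and -1.47 in the authors' deposited table, and their listed averages summed to 123, 151 and 156, against 263 or more in every other cluster. Of the remaining lists, extracellular matrix, interferon and antiviral, inflammatory cytokines and chemokines, immediate early, and cholesterol synthesis had no member in the table.

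Profiles over the 218 genes were compared between clusters. The lowest Pearson correlation within clusters 8, 12, 14, 19 and 21 was 0.93 (Spearman 0.94), and within clusters 7, 9 and 11 it was 0.87 (0.87). Between these sets the Pearson correlation ran from -0.03 to 0.38 and the Spearman correlation from 0.00 to 0.43. Cluster 5, also cardiomyocyte-like, is in neither set and lay between them. Its Pearson correlations were 0.49, 0.55, 0.50, 0.58 and 0.53 with clusters 8, 12, 14, 19 and 21, and 0.83, 0.77 and 0.72 with clusters 7, 9 and 11. Clusters 5 and 20 correlated at 0.94 (0.96), clusters 1 to 4, 18 and 22 to 24 at 0.94 (0.92) or more, and clusters 15 to 17 at 0.86 (0.83) or more. The sets were chosen after the values were seen, and genes are not independent replicates. The highest correlation between the first pair of sets turned to -0.05 with the 109 genes of higher mean average.

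**Figure D5:**
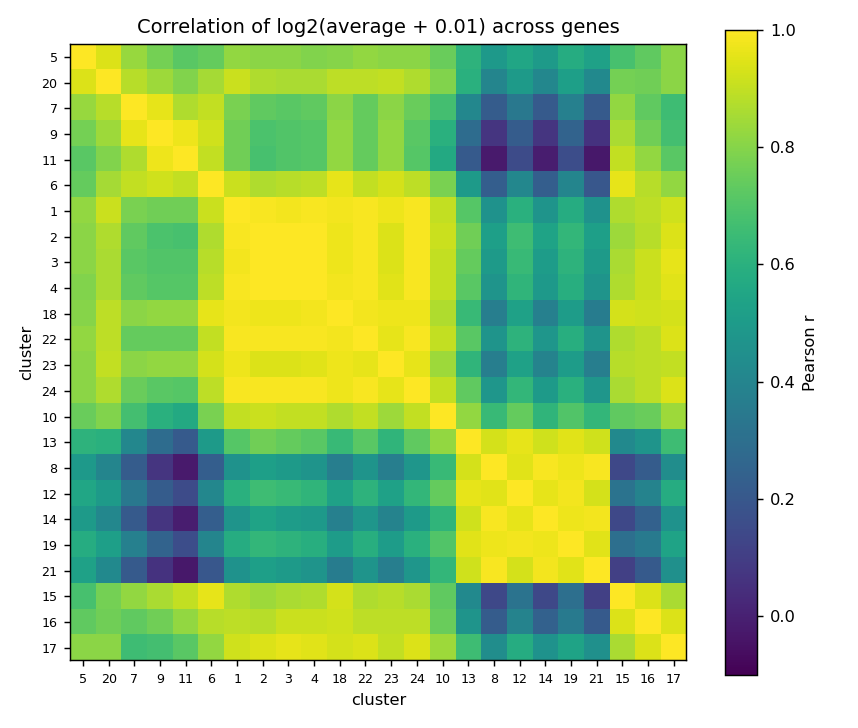
Pearson correlation (colour) of log2(average + 0.01) across the 218 genes between each pair of the 24 clusters (both axes, ordered by similar profile). The block of clusters 8, 12, 14, 19 and 21 stands at 0.93 or more, and its correlations with clusters 7, 9 and 11 stand at 0.38 or less. Its correlations with cluster 5 stand at 0.49 to 0.58.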

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

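The comparison against 9 clusters and the lists without 5 genes led by Gm42418 were chosen after the data were seen; the other alternatives were planned. No paired analysis was possible because each group has 1 library and the table names neither, and there was no replicate to leave out. Of 544 values recomputed under an alternative, 470 kept their place, that is the side of the middle and of the threshold for a percentile, or stayed within 1.5 times for a count or 0.1 for a correlation. The oxidative phosphorylation list in the 10 clusters recomputed and the heat shock list in clusters 5, 7 and 9 kept their side of the threshold under each alternative run.

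With an absolute log2 fold change of at least 1, the 1801 calls became 992 and the 632 higher calls became 113. Counts higher became 6 in cluster 1, 3 in cluster 5, 23 in cluster 7, 3 in cluster 8, 13 in cluster 9, 7 in cluster 11, 0 in cluster 12, 1 in cluster 14, 1 in cluster 19 and 7 in cluster 21; counts lower became 5 in cluster 5, 13 in cluster 7 and 20 in cluster 9. The filter on mean average left 109 genes to call, fewer by construction, and gave 875 calls, 306 higher and 569 lower. Counts higher became 5 in cluster 1, 33 in cluster 5, 31 in cluster 7, 69 in cluster 8, 28 in cluster 9, 6 in cluster 11, 0 in cluster 12, 38 in cluster 14, 1 in cluster 19 and 68 in cluster 21. Counts lower became 32 in clusters 5, 7, 14, 19 and 21, 34 in cluster 8, 67 in cluster 9, 78 in cluster 11 and 36 in cluster 12. At p of 0.01, 5 genes were higher in cluster 1, 0 in cluster 12 and 25 in cluster 14, and 32 were lower in cluster 5. At p of 0.1, 23 were higher in cluster 1 and 4 in cluster 12.

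For the lists, percentiles moved across the limits or the middle as follows, and the cause was not tested. The cardiomyocyte list in cluster 1 fell inside the central range with unmatched lists (95.6) and with the filter (96.2), and the sarcomere list in cluster 5 did with unmatched lists (97.0). The cardiomyocyte list in cluster 11 did with the filter (96.6), and the ribosomal list in cluster 9 with a pseudocount of 1 (3.87). Ratios of averages with pseudocounts of 0.01, 0.1 and 1 put the cardiomyocyte list in cluster 5 at 99.9, 99.9 and 99.8 (99.3 with the filter). They put the sarcomere list in cluster 1 at 100.0 each time, and reversed the fetal or stress list in cluster 5 to 98.4, 97.9 and 99.7, and in cluster 7 to 87.2, 85.9 and 79.0, inside the central range. The heat shock list, inside that range throughout in clusters 1, 8, 11 and 21, reversed in cluster 1 to 81.3, 71.6 and 70.3, and with the filter to 50.4. It also reversed in cluster 8 to 50.2 with unmatched lists, and in clusters 11 and 21 to 61.7 and 37.7 with the filter. The medians themselves moved more: in 12 cases the sign of a median turned while its percentile kept its side. In 3 more cases both turned, all for the fetal or stress list in cluster 7, whose median went from -0.08 to 0.83, 0.71 and 0.29 with the ratios. The ratios turned oxidative phosphorylation in cluster 11 from -0.03 to 0.16, 0.11 and 0.01, heat shock in cluster 8 from -0.08 to 0.26, 0.24 and 0.09 and in cluster 14 from -0.12 to 0.26, 0.22 and 0.07 (0.01 with the filter). Ribosomal proteins in cluster 5 went from -0.17 to 0.06 and 0.04, and the cardiomyocyte list in cluster 11 from 0.33 to 1.14, 1.04 and 0.64. In cluster 1 the ratios reversed the fetal or stress list to 94.7, 93.3 and 86.8, and it stood at 2.55 without the 5 genes and 7.03 against the 9 clusters. The highest correlation between clusters 8, 12, 14, 19 and 21 and clusters 7, 9 and 11 reversed to -0.05 with the filter. The clusters with the fewest counts, 22 to 24, with 0.0617%, 0.0532% and 0.0318% of the weight, had no gene called.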

Other observations

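Apart from the test of mixed droplets in clusters 1 to 4, 18 and 22 to 24, whose prediction was written before its result was seen, the tests in this part were chosen only after the results were seen, as were the ratios between pairs of clusters.

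Cluster 5 and cluster 7 were the cardiomyocyte-like clusters of largest weight, and they differed in few of the listed genes. Between them 200 genes lay within 2-fold, 14 were at least 2 times higher in cluster 5 and 4 were at least 2 times higher in cluster 7. Cluster 5 had 26.9 times the Hmgb2 of cluster 7 (95% interval 25.8 to 28.1), 26.6 times the Ccnd1 (25.8 to 27.4) and 6.29 times the H2afz, a histone variant (6.19 to 6.39). It had 5.28 times the Hsp90aa1, 4.18 times the co-chaperone gene Dnaja1, 4.14 times the Hmgb1, and 3.83 times the Ran-binding gene Ranbp1. The muscle genes Csrp3 and Actc1 stood at 0.447 and 0.484 times their level in cluster 7, and AY036118 and Gm42418 at 0.377 and 0.474. Cluster 20, with 0.651% of the weight and no gene called in either direction by the authors' p, had 25.8 times the Hmgb2 of cluster 7 (24.4 to 27.3) and 25.7 times the Ccnd1 (24.8 to 26.7), with an average of Tnnt2 of 14.4 against 15.2 in the authors' deposited table. These intervals cover counting error only.

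The clusters low in muscle genes held a like pair. Between clusters 21 and 8, 216 of the 218 genes lay within 2-fold, and the 2 that did not were Ccnd1, at 3.57 times in cluster 21 (95% interval 3.53 to 3.60), and Hmgb2, at 2.06 times (2.03 to 2.08).

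Ccnd1 and Hmgb2 were higher in clusters 5 and 20 than in clusters 7, 9 and 11. Mixing with cluster 21, where both were also high, is argued against for cluster 5 as the whole of the pattern. Set against clusters 7, 9 and 11 in turn, the other genes apart by at least 2 times would need median shares of 26.6% to 41.6%. Their upper quartiles reached 48.9%, while Ccnd1 and Hmgb2 needed 61.3% to 63.6%. Still, 9 to 17 of the 132 to 170 other genes needed as much as Ccnd1. The highest share among the 11 cardiomyocyte markers was 57.4%, 58.7% and 51.8% against clusters 7, 9 and 11, not far below that of the 2 genes. A smaller share of cluster 21 in cluster 5 stays open. For cluster 20 the shares point both ways, so mixing is not settled there. At the scale of the table the 2 genes needed 58.5% to 61.4%, and none of the 11 cardiomyocyte markers needed more than 32.9%. Over the other genes, however, the median share was 6.96% against cluster 7, 40.6% against cluster 9 and 61.9% against cluster 11. The upper quartiles were 43.8%, 64.2% and 75.1%. As much as Ccnd1 was needed by 10 of 132 genes against cluster 7, 49 of 170 against cluster 9 and 86 of 167 against cluster 11. A difference of scaling between clusters would move all listed genes of a pair alike, so by its nature it cannot be the whole of the pattern. Over the 6 pairs of cluster 5 or 20 with cluster 7, 9 or 11, the median log2 ratio of the listed genes ran from -0.07 to 1.34. Ccnd1 and Hmgb2 both stood above every other listed gene and at least 2.17 above the median of their pair. The 2 genes were set as the pattern after their values were seen, so their rank above the others adds no support. The 4F adenovirus, which carries a D cyclin, may account for the pattern as a biological or a vector-derived difference, but 0 columns name a library, so this cannot be told apart from other differences between cells.

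Gm42418, AY036118, Cdk8, Cmss1 and Camk1d each had a log2 fold change of 1.57 or more in clusters 1 to 4, 6, 10, 18 and 22 to 24 of the authors' deposited table; all 5 passed at p of 0.05 or less in clusters 1 to 4, 6 and 10, 3 passed in cluster 18 and none in clusters 22 to 24. A source of reads that adds Gm42418 and AY036118 in 1 fixed ratio stays open: over these 10 clusters their ratio of counts ran from 6.25 in cluster 1 (95% interval 6.20 to 6.30) to 9.95 in cluster 23 (9.47 to 10.5), and the spread was 1.61 to 1.74 times with 1 common baseline taken off but 1.28 times with a baseline picked for each cluster to bring the ratios closest, and the true baselines are not known. Free RNA or mixed droplets stay open. Mixes of the 9 clusters of largest weight were fitted to the other genes only. The median absolute log2 misfit was 0.103 to 0.151 in clusters 1 to 4, 18 and 22 to 24. In clusters 6 and 10 it was 0.0798 and 0.122. These values lie within the 0.0794 to 0.247 of the 9 clusters each rebuilt from the others, which decides neither way. The 5 genes were left out of the mixes, so the misfits do not bear on them. Whether a mix could reach the levels of the 5 genes was not tested. Few counts per cell stay open as well, since the weight of cluster 5 was 21.8 times that of cluster 1 and the number of cells in each is not known. No biological explanation was tested.

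The listed genes were low together in clusters 15 to 17. Mitochondrial transcripts that take up the counts of damaged cells are a possible explanation, and mt-Nd6 had a median log2 fold change of 1.67 over these clusters in the authors' deposited table. With 1 mitochondrially encoded gene listed this stays open, and mt-Nd6 was also higher in clusters 9 and 11. No biological explanation was tested.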
